A study of Mus musculus with 15 samples.

How the data were processed

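Single-cell RNA sequencing was done on the 10x Genomics platform from layer 5 of the primary motor cortex of C57BL/6 mice of 8 to 10 weeks, with males and females pooled per the labels. Corticospinal neurons (CSN), which send their axons from the cortex to the spinal cord, were labelled by a retrograde adeno-associated virus coding for GFP. The virus was injected into the cervical cord (forelimb, FL) or the lumbar cord (hindlimb, HL), and tissue was taken 10 days later. Cells of at least 10 µm in diameter were sorted by fluorescence into CSN and non-CSN fractions, which gave 3 libraries for each of FL CSN, FL non-CSN, HL CSN and HL non-CSN. A further 3 libraries came from mice in which Rbp4-Cre switches on tdTomato from the Ai14 allele in layer 5 neurons: FL positive, HL positive, and a negative fraction of both, with 1 library each. Nothing in the labels says that replicates were separate animals, so the p-values measure the spread between these libraries, some of which may be technical.

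The deposited matrices hold raw UMI counts per gene and cell with no normalisation. Per the file headers the authors made them with Cell Ranger 7.1.0, and per the labels they mapped reads to mm10. The barcodes are those of the filtered Cell Ranger output. Each library's matrix was present in 2 copies with equal entries, of which 1 was used. Of 28000 features, 27998 were mouse genes and the others were the reporters eGFP and tdTomato. Gene positions were taken from GENCODE vM21 (GRCm38), which held 27645 of the identifiers, 26501 of them with the same symbol. All positions are on that build.

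Barcodes with at least 500 genes, at least 1000 UMIs and at most 20% of UMIs from mitochondrial genes were kept, 21072 of 37331. Doublet scores were computed per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 barcodes loaded, which took out 788 barcodes (3.74%) and left 20284 cells. All libraries were clustered together on log-normalised counts with 2000 variable genes, 30 principal components, 15 neighbours and the Leiden algorithm (leidenalg 0.10.2) at resolution 1, without correction between libraries. Each of the 28 clusters was named from marker lists fixed before the data were examined. A class needed 3 markers detected in at least 10% of a cluster's cells and, for classes other than the general excitatory one, at least 1.5-fold above the other clusters with 5 CPM (counts per 1000000) added. The candidate with the highest mean standardised marker level gave the name. Excitatory clusters that met no subclass were called unresolved. Classes carry the suffix "-like" because they rest on transcripts alone: intratelencephalic (IT), extratelencephalic (ET, the class that includes corticospinal neurons), corticothalamic (CT) and near-projecting (NP) neurons.

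Shares of the 17 classes were compared between libraries by exact two-sided permutation tests of the difference of means. With 6 against 6 libraries there were 924 arrangements and the smallest possible p was 0.00216; with 3 against 3 there were 20 arrangements and the smallest was 0.1. Intervals on shares of 1 library are exact Clopper-Pearson 95% intervals and those on reporter counts are exact Poisson 95% intervals. They cover counting error only. A count of 0 is given with the upper limit of 3 counts. The L5 ET-like precision was set by the number of kept cells, from 76 to 4134 per library.

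For gene tests, UMI counts were summed per library over the cells of a class in libraries with at least 10 such cells. Genes were kept by the filterByExpr function of edgeR 4.0.16, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted and tested two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The CSN against non-CSN model had a limb term. FL against HL was tested within CSN and within non-CSN libraries, and the interaction compared these limb effects. Values are CPM as mean ± SD over libraries and log2 fold change ± SE. The libraries were the replicates, and cells were not. Within each limb, the CSN and non-CSN libraries of the same number correlated best with each other in all 6 cases (r = 0.506 to 0.915 across genes, after the group mean was removed), so a model with a term for each pair is given beside the CSN against non-CSN values. Between limbs the same number gave r from -0.459 to 0.588, and no pairing was taken.

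On simulated data made from these libraries, with 200 genes changed, the CSN against non-CSN model for excitatory-like cells recovered 73% of genes changed 2-fold and 94% of those changed 4-fold, with 4 false calls. With the pair term these were 65% and 91%. No correlation between the members of a pair was simulated, so these values do not describe the pair term on the real libraries. In L5 ET-like cells the sort comparison recovered 7% and 58%, and the limb comparison 8% and 72%. In excitatory-like cells the limb comparison recovered 20% and 93% in CSN libraries and 10% and 78% in non-CSN libraries, and the interaction 3% and 55%.

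The 22 gene lists were fixed before the data were examined: segmental corticospinal markers, L5 ET identity, upper layer and IT identity, neurofilament and axonal cytoskeleton, potassium and HCN channels, sodium and calcium channels, glutamate receptors, GABA receptors, monoamine and acetylcholine receptors, axon guidance, cadherins and protocadherins, cortical area patterning, axon growth and injury response, immediate early and dissociation stress genes, interferon response and antigen presentation, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, and markers of astrocytes, oligodendrocytes, microglia, endothelium and inhibitory neurons. The L5 ET, upper layer and glial lists share members with the markers that named the clusters. They were tested with camera of limma 3.58.1 on log2 CPM (2 counts added) with a preset correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run as alternatives.

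Genes were named by a rule set before the data were examined. In each direction it took up to 8 genes with the largest change among those that passed, had a mean log2 CPM of at least 4 and lay above the other group's median in every library of the higher group. Where fewer than 5 passed, it took the 5 with the lowest p-values. Predicted genes, Rik clones, ribosomal, mitochondrial, Xist and Y-linked genes were left out. Klhl14, Crim1 and Cbln1 were named in every limb comparison, with up to 4 members of each list and the reporters. After the data were seen, the same rule was also applied to the model with the pair term.

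Alternatives planned before the data were examined were RLE size factors, DESeq2 1.42.0, limma voom with sample weights, no filter on low counts, no cell filter, a stricter one (1000 genes, 10% mitochondrial), doublets kept, resolutions 0.5 and 2, at least 30 cells per library, the pair term, single-limb fits, 1 model for 4 groups, and leaving out each library. Chosen after seeing the data were cells with at least 5000 UMIs, sums without L5 ET-like cells, sums of L4/5 IT-like, L6 CT-like or single-cluster cells, and a covariate for the division of the libraries described among the other observations. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. The Rbp4 libraries were left out of all tests between groups, because each group had 1 library. No background removal, trajectory or RNA velocity step was used here.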

Results

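The series asks how corticospinal neurons that serve the forelimb and the hindlimb differ from each other and from neighbouring layer 5 cells of the adult mouse motor cortex. It holds 15 droplet single-cell libraries: 3 each of FL CSN, FL non-CSN, HL CSN and HL non-CSN cells from retrograde labelling, and 3 from Rbp4-Cre:Ai14 mice. Total UMIs in the FL CSN replicates 1 to 3 were 19062365, 10576890 and 3577074, and in the FL non-CSN replicates 23542214, 2905395 and 1178333. They were 11835437, 14535524 and 11318556 in the HL CSN replicates and 9485185, 103293037 and 8862988 in the HL non-CSN replicates. The Rbp4 libraries had 16728930 (labelled FL positive), 27628886 (labelled HL positive) and 31508124 UMIs (labelled negative). Median UMIs per barcode ran from 891 in the library labelled HL positive to 17717 in HL non-CSN replicate 2. Kept cells in the same order of replicates numbered 1325, 806 and 240 (FL CSN), 3726, 250 and 76 (FL non-CSN), 713, 612 and 720 (HL CSN), and 561, 4134 and 494 (HL non-CSN). The Rbp4 libraries kept 1900 (FL positive), 2389 (labelled HL positive) and 2338 cells (labelled negative). Mitochondrial transcripts took 5.10%, 8.31% and 13% of UMIs in the FL CSN replicates and 11.6%, 15.4% and 4.33% in the HL CSN replicates. In the non-CSN libraries they took 6.00%, 4.4% and 3.67% (FL) and 5.49%, 4.64% and 2.78% (HL).

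The reporter transcripts were counted in each library and set beside its label. The retrograde reporter eGFP was found at 18.2 UMIs per 1000000 (CPM; 346 UMIs, 95% interval 16.3 to 20.2) in FL CSN replicate 1. The other CSN libraries had 0.0945 (FL replicate 2), 0.839 (FL replicate 3), 0.338 (HL replicate 1) and 0.344 (HL replicate 2), and HL CSN replicate 3 had 0, which allows up to 0.265. Of the non-CSN libraries, HL replicate 2 had 7 eGFP UMIs (0.0678, 0.0272 to 0.140) and the others none. Within FL CSN replicate 1, L5 ET-like cells had 162 eGFP CPM (144 to 183), with a UMI in 46 of 158 cells at a median depth of 2036.5 UMIs. Its other excitatory-like cells had 1.68 (1.07 to 2.49; 22 of 844 cells, median depth 17728). Its inhibitory-like cells, which do not project to the cord, had 4.63 (2.12 to 8.79; 9 of 250 cells, median depth 1444.5). In the other CSN libraries eGFP RNA was near or under the limit of detection, so the label of single cells could not be read from it. Depth alone does not account for this, since L5 ET-like cells of HL CSN replicate 2 held 1 eGFP UMI in 2141600 (0.467 CPM, 0.0118 to 2.60) and those of FL CSN replicate 1 held 273 in 1681245.

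In the Rbp4 libraries, tdTomato stood at 29.2 CPM in the FL positive library (488 UMIs, 26.6 to 31.9). It stood at 26.2 (827 UMIs, 24.5 to 28.1) in the library labelled negative and at 0.217 (6 UMIs, 0.0797 to 0.473) in the library labelled HL positive. The non-CSN libraries, which carry no Ai14 allele per the labels, had at most 15 UMIs, and the highest upper limit among them was 2.55 (FL replicate 3, with a count of 0). tdTomato therefore went against the labels of 2 Rbp4 libraries, and these are named only by their labels.

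**Figure D1:**
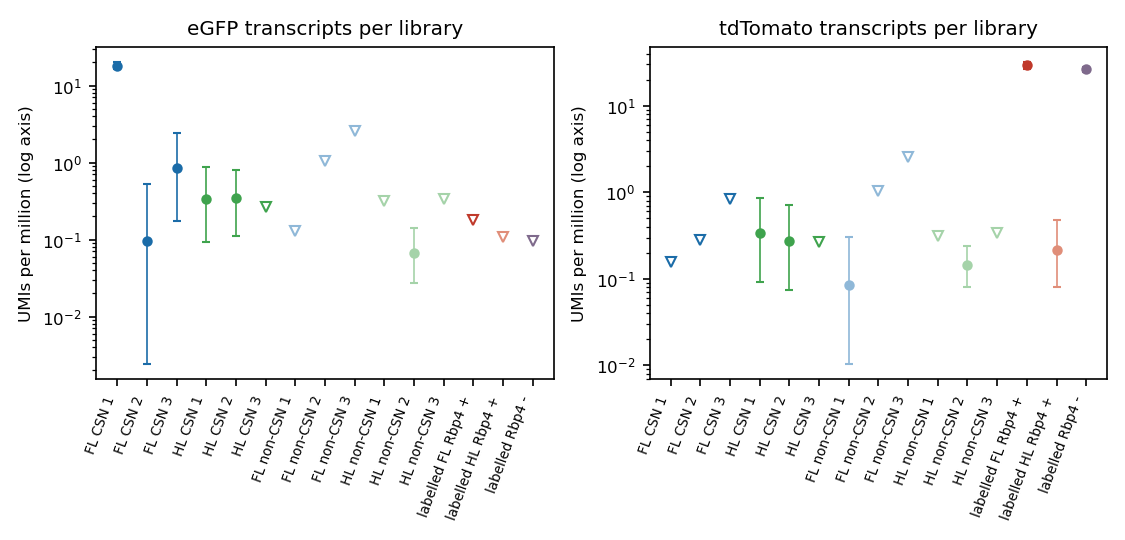
eGFP (left) and tdTomato (right) in CPM on log axes, 1 point per library with its exact 95% Poisson interval; open triangles mark the upper limit for a count of 0. FL CSN replicate 1 had 18.2 eGFP CPM, and tdTomato stood at 29.2 in the FL positive library, 26.2 in the library labelled negative and 0.217 in the library labelled HL positive.

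Whether the sort enriched the class that holds corticospinal neurons was asked from the share of cells per class. L5 ET-like cells, marked by Fezf2, Bcl11b, Pou3f1 and Fam84b, made up 5.94% ± 4.60 of kept cells in CSN libraries and 0.350% ± 0.330 in non-CSN libraries (SD, n = 6 and 6). Their share was above the non-CSN median in 6 of 6 CSN libraries. Inhibitory-like cells stood at 15.4% ± 5.93 against 8.41% ± 2.47, and macrophage-like cells at 6.21% ± 11.7 against 0.349% ± 0.678. Oligodendrocyte-like cells stood at 0.757% ± 0.53 against 2.77% ± 2.45. L2/3 IT-like cells were 12.6% ± 4.4 against 20.5% ± 15, L4/5 IT-like cells 21.8% ± 5.89 against 25.7% ± 12, L6 CT-like cells 15.6% ± 10.3 against 17.5% ± 6.06, and L6 IT-like cells 8.90% ± 3.29 against 6.85% ± 4.49.

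None of the 17 classes passed after adjustment, and 4 lay at an unadjusted p under 0.05 in the exact two-sided permutation test. For L5 ET-like cells the difference was 5.59 percentage points with an exact p = 0.00433 (adjusted 0.0736). For inhibitory-like cells the exact p was 0.0238 (adjusted 0.202), for macrophage-like cells 0.0390 (adjusted 0.212) and for oligodendrocyte-like cells 0.0498 (adjusted 0.212). With pairs of libraries as blocks each of these 4 reached the smallest possible exact p of 0.03125 (adjusted 0.133). Without FL CSN replicate 2, which had 0.620% L5 ET-like cells, the L5 ET-like difference was 6.65 and passed (adjusted p = 0.0368, exact permutation). It also passed at resolution 2 (adjusted p = 0.0368), as did 1 class outside these 4. Macrophage-like cells passed with no cell filter (adjusted p = 0.0411) and with the stricter filter (0.0368), but their difference was 1.09 percentage points without HL CSN replicate 2 and turned to -0.273 with doublets kept, where 1 class outside these 4 passed. Oligodendrocyte-like cells passed among cells with at least 5000 UMIs (-1.48 points, adjusted p = 0.0368).

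**Figure D2:**
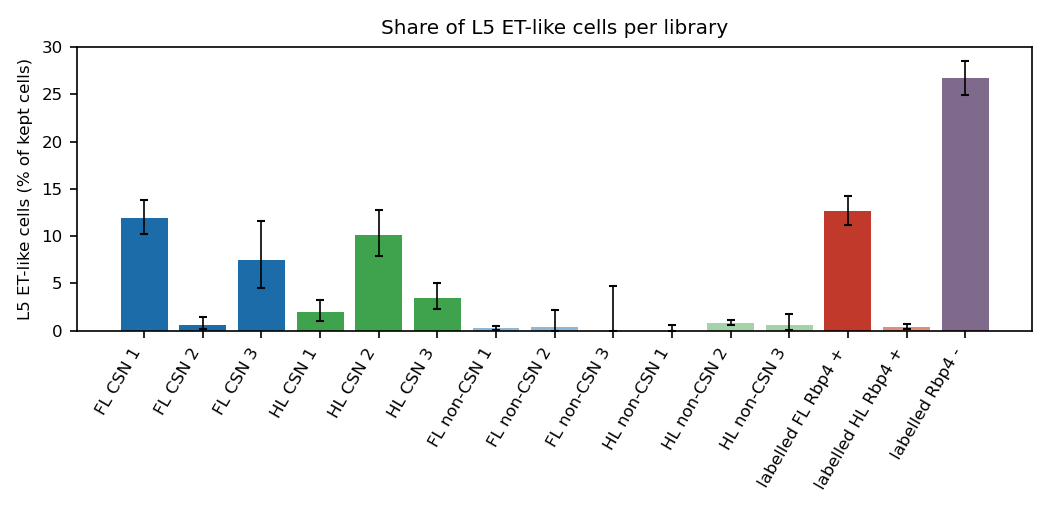
L5 ET-like cells as percent of kept cells in each of the 12 retrograde libraries and 3 Rbp4 libraries, with exact Clopper-Pearson 95% intervals as bars. CSN libraries ran from 0.620% to 11.9% and non-CSN libraries from 0 to 0.822%.

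Single CSN libraries differed widely. L5 ET-like cells were 11.9% (158 of 1325, 10.2 to 13.8), 0.620% (5 of 806, 0.202 to 1.44) and 7.5% (18 of 240, 4.51 to 11.6) in FL CSN replicates 1 to 3. They were 1.96% (14 of 713, 1.08 to 3.27), 10.1% (62 of 612, 7.86 to 12.8) and 3.47% (25 of 720, 2.26 to 5.08) in HL CSN replicates 1 to 3. Non-CSN libraries had 0.268%, 0.400% and 0 of 76 cells (up to 3.95%) for FL, and 0 of 561 cells (up to 0.535%), 0.822% and 0.607% for HL. Between limbs, L5 ET-like cells were 6.68% ± 5.70 of FL CSN and 5.19% ± 4.35 of HL CSN libraries (n = 3 and 3; exact permutation p = 0.8). None of the 17 classes lay at an unadjusted p under 0.05, since the smallest p for this design was 0.1, and the lowest found was 0.2 for microglia-like cells. The L5 ET-like difference of 1.49 points changed sign without FL CSN replicate 1 (-1.13) and without HL CSN replicate 1 (-0.120), and also as a share of excitatory-like cells (-1.91).

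CSN and non-CSN libraries were next compared over the summed excitatory-like cells. The secreted ligand gene Wnt7b (ENSMUSG00000022382, chromosome 15, 85535437 to 85582473) rose in CSN libraries, with 25.6 ± 4.11 CPM against 10.4 ± 1.76 (log2 1.25 ± 0.15, adjusted p = 0.0155). It lay above the non-CSN median in 6 of 6 CSN libraries. With the pair term, the proline transporter gene Slc6a7 (ENSMUSG00000052026, chromosome 18, 60995380 to 61014222) rose by 0.90 ± 0.11 on the log2 scale (101 ± 22.0 against 52.9 ± 7.85 CPM; adjusted p = 0.00469). Deptor, an mTOR inhibitor (ENSMUSG00000022419, chromosome 15, 55112317 to 55259271), rose by 0.88 ± 0.16 (86.8 ± 9.01 against 45.5 ± 14.8; 0.0435), and the heparan sulfatase gene Sulf2 (ENSMUSG00000006800, chromosome 2, 166073089 to 166155663) by 0.90 ± 0.11 (105 ± 29.6 against 54.1 ± 8.89; 0.00469). The layer 5 transcription factor gene Etv1 (ENSMUSG00000004151, chromosome 12, 38779380 to 38870484) rose by 1.09 ± 0.19 (145 ± 67.4 against 65.2 ± 22.2; 0.0468).

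Lower in CSN libraries with the pair term were Slc17a6, which codes for the vesicular glutamate transporter VGLUT2 (ENSMUSG00000030500, chromosome 7, 51622006 to 51671119), Pcdh20, a protocadherin (ENSMUSG00000050505, chromosome 14, 88464743 to 88471396), and Cbln4, a synaptic organiser (ENSMUSG00000067578, chromosome 2, 172036233 to 172043466). Slc17a6 fell by 0.95 ± 0.089 (23.0 ± 12.6 against 43.8 ± 23.4 CPM; adjusted p = 0.000968). Pcdh20 fell by 1.23 ± 0.16 (15.3 ± 6.49 against 38.3 ± 19.1; 0.00663) and Cbln4 by 1.08 ± 0.18 (11.5 ± 4.97 against 25.9 ± 5.71; 0.0215). The Wnt pathway modulator gene Dact2 (ENSMUSG00000048826, chromosome 17, 14195052 to 14204304) fell by 0.91 ± 0.12 (31.9 ± 11 against 63.7 ± 30.6; 0.00854), and Tmem215 (ENSMUSG00000046593, chromosome 4, 40472180 to 40477168) by 0.76 ± 0.13 (22.1 ± 3.09 against 38.7 ± 11.3; 0.0204). The other genes that the rule named with the pair term were Parm1 (1.69 ± 0.29), Tmem91 (1.05 ± 0.17) and Plcxd3 (0.92 ± 0.12), higher in CSN, and Btbd3 (-0.69 ± 0.096), Pcna (-0.66 ± 0.13) and Prdm8 (-0.65 ± 0.12), lower.

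**Figure D3:**
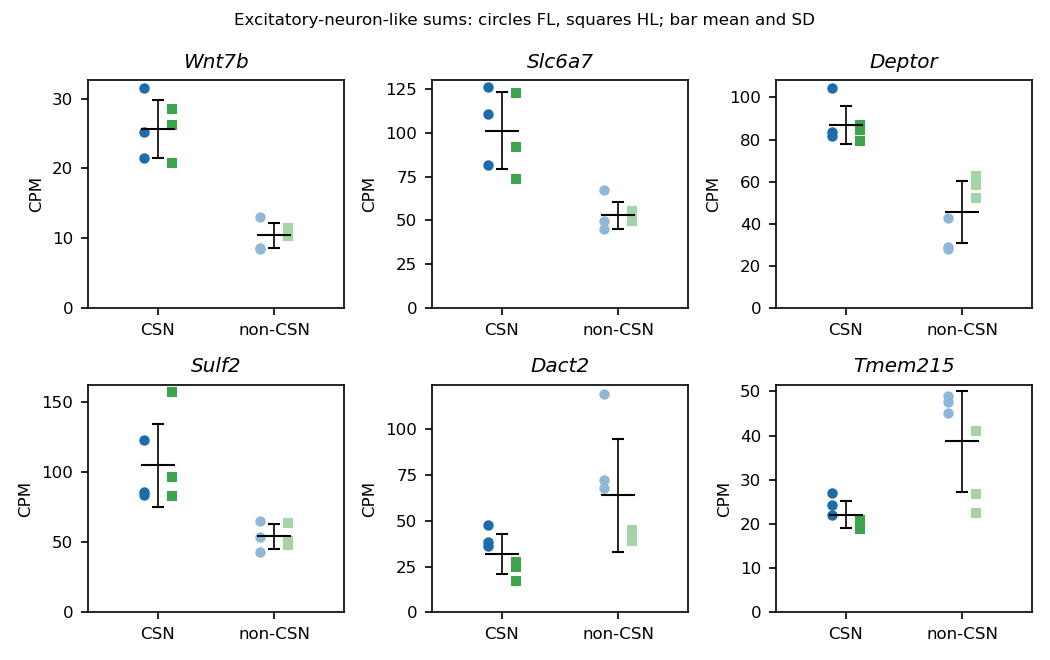
CPM of Wnt7b, Slc6a7, Deptor, Sulf2, Dact2 and Tmem215 in summed excitatory-like cells, 1 point per library (circles FL, squares HL) with mean and SD bars for 6 CSN and 6 non-CSN libraries. Wnt7b had 25.6 ± 4.11 CPM in CSN and 10.4 ± 1.76 in non-CSN libraries.

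In edgeR without the pair term, 1 of 12806 genes passed, Wnt7b. At an unadjusted p under 0.05 lay 305 higher and 299 lower genes, fewer in all than the share of 0.05 that chance gives. With the pair term 46 genes were higher and 43 lower, Wnt7b among them (1.22 ± 0.12, adjusted p = 0.00111). DESeq2 called 24 genes and limma voom 9. Among the genes named without the pair term as not passing, Slc6a7 had an adjusted p of 0.247, Deptor 0.288, Sulf2 0.321, Plcxd3 0.337, Tmem91 0.400, Dact2 0.25, Tmem215 and Btbd3 0.321, Jdp2 0.337 and Nme2 0.405. Wnt7b missed the threshold when any of 8 libraries was left out: FL CSN replicate 3 (adjusted p = 0.0519), FL non-CSN replicates 2 (0.0553) and 3 (0.0594), HL CSN replicates 1 (0.0925) and 2 (0.0754), and HL non-CSN replicates 1 (0.101), 2 (0.0914) and 3 (0.0546). Wnt7b, Deptor and Tmem91 were among the 10 leading genes of cluster 6, 1 of 4 L4/5 IT-like clusters. Pcdh20 and Cbln4 were among those of cluster 4, another L4/5 IT-like cluster, and Parm1 among those of the L5 ET-like clusters 8 and 14. The mix of the L4/5 IT-like clusters and the L5 ET-like share differed between sorts, so these changes are not separated from the mix of cells. Within cluster 6 alone the Wnt7b difference was 0.42, within cluster 7 it was 1.05 and within L6 CT-like cells 0.55, none of which passed.

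By lists, the 9 tested of 10 L5 ET identity genes were all higher in CSN libraries, with a median log2 change of 0.82, and the list rose as a set (camera adjusted p = 1.07e-05; adjusted p = 0.339 with an estimated correlation). They included Fam84b (2.29 ± 0.73), Pou3f1 (0.95 ± 0.43), Fezf2 (0.82 ± 0.29; 59.0 ± 30.6 against 33.7 ± 11.3 CPM) and Npr3 (0.70 ± 0.33), none of which passed without the pair term, adjusted over the list alone or over all genes. Fam84b passed over all genes with the pair term (2.50 ± 0.45, adjusted p = 0.0348). The L5 ET-like share differed by 5.59 points in the same libraries, and without L5 ET-like cells the median of the 7 genes still tested was -0.01 (0.82 for the same 7 with them). All 13 mitochondrially encoded genes were higher (median 0.50; camera adjusted p = 1.07e-05; adjusted p = 0.339 with an estimated correlation), such as mt-Nd1 (0.79 ± 0.27; 7020 ± 3068 against 4036 ± 721 CPM), mt-Co2 (0.62 ± 0.23) and mt-Nd4 (0.63 ± 0.24). Mitochondrial transcripts took 4.33% to 15.4% of UMIs in CSN and 2.78% to 6.00% in non-CSN libraries. The segmental corticospinal markers Crim1 (0.55 ± 0.24; 49.5 ± 20.6 against 32.9 ± 10.1 CPM) and Cbln1 (1.09 ± 0.49; 10.0 ± 7.48 against 4.05 ± 2.26) rose as a set (camera adjusted p = 0.0417; adjusted p = 0.339 with an estimated correlation), and 2 of 2 passed adjusted over the list alone. The set did not pass with the pair term (adjusted p = 0.0979) or with the library covariate (0.0952). Monoamine and acetylcholine receptor genes rose as a set, with 14 of 20 above 0 and a median of 0.18 (camera adjusted p = 0.0417; adjusted p = 0.339 with an estimated correlation), among them Adra1b (0.58 ± 0.21), Htr1b (0.66 ± 0.28) and Chrnb2 (0.29 ± 0.16). The receptor set did not pass with the library covariate (0.0505). No gene of the mitochondrial or receptor list passed adjusted over the list alone without the pair term, and with it Adra1b passed over all genes (0.61 ± 0.12, adjusted p = 0.0405).

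Of the other 18 lists none passed without the pair term. Nuclear oxidative phosphorylation genes had 29 of 36 below 0 (median -0.11; camera adjusted p = 0.330) and fell as a set with the pair term (adjusted p = 0.0250; adjusted p = 0.834 with an estimated correlation). Upper layer and IT genes had 11 of 17 below 0 (adjusted p = 0.599). Adjusted over the list alone, Deptor and Etv1 of that list passed as higher and Calb1 (-1.13 ± 0.30) and Rspo1 (-0.90 ± 0.31) as lower, as did Etv1 of the area patterning list (6 of 17 above 0; 0.599). Potassium and HCN channels had 1 lower gene adjusted over the list alone and 18 of 39 above 0 (adjusted p = 0.522), with a median of -0.02, a mean of 0.07 and a test in the upward direction. Over all genes and with the pair term, 1 gene fell in each of the oxidative phosphorylation, axon guidance, cadherin and interferon lists, and 1 rose and 1 fell among potassium and HCN channels. In the upper layer and IT list Deptor and Etv1 rose and Cux1 fell (-0.74 ± 0.11, adjusted p = 0.0105) in that fit. Etv1 counts for the area patterning list too. For each of the next lists 0 genes passed adjusted over the list alone without the pair term. Above 0 were 13 of 21 neurofilament and cytoskeleton genes (adjusted p = 0.251), 15 of 22 sodium and calcium channels (0.522), 15 of 21 glutamate receptors (0.251), 7 of 14 GABA receptors (0.534), 30 of 45 axon guidance genes (0.330), 12 of 21 cadherins (0.402), 13 of 18 axon growth genes (0.330), 10 of 19 immediate early genes (0.667) and 5 of 11 interferon genes (0.402). Among markers of other cells the adjusted p was 0.402 for astrocytes (3 genes), 0.972 for oligodendrocytes (3), 0.402 for microglia (1), 0.972 for endothelium (2) and 0.522 for inhibitory neurons (7). The astrocyte (median -0.20, mean -0.21) and inhibitory lists (median -0.46, mean -0.30) had negative medians and means but a test in the upward direction, and in the latter Pvalb stood at 1.79 ± 0.83 and Npy at -1.33 ± 0.60.

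Within L5 ET-like cells, 5 CSN libraries (FL replicates 1 and 3, HL replicates 1 to 3) were compared with the 2 non-CSN libraries that had at least 10 such cells: FL replicate 1 (10 cells) and HL replicate 2 (34 cells). The class pools 2 clusters, and their mix was not constant. The shallow cluster 8 (median 1655 UMIs) held 90.0% of these cells in FL non-CSN replicate 1, 23.5% in HL non-CSN replicate 2 and 3.23% to 69.6% in the CSN libraries. The gene differences below are not separated from this mix. FL non-CSN replicate 1 had 45723 UMIs in these cells, where a count of 0 allows up to 65.6 CPM. The non-CSN means of Cdh13, St6galnac5 and Ramp3 lay under that limit, so they rest on few counts in that library. The adhesion gene Cdh13, which codes for T-cadherin (ENSMUSG00000031841, chromosome 8, 118283733 to 119324921), rose in CSN libraries, with 129 ± 57.6 CPM against 15.9 ± 8.43 (log2 3.14 ± 0.55, adjusted p = 0.0488). Higher without passing were the sialyltransferase gene St6galnac5 (ENSMUSG00000039037, chromosome 3, 152817081 to 152982246; 2.37 ± 0.49, 238 ± 130 against 29.9 ± 11.4 CPM, adjusted p = 0.199) and Ramp3, which codes for a partner of calcitonin-family receptors (ENSMUSG00000041046, chromosome 11, 6658521 to 6677475; 2.84 ± 0.60, 67.6 ± 37.2 against 13.8 ± 11.4, 0.203). Nfia (1.98 ± 0.46), Tns1 (3.53 ± 0.85) and Serpina3n (4.80 ± 1.14) followed, with adjusted p of 0.377, 0.377 and 0.390. Camk2n2, an inhibitor of CaMKII (ENSMUSG00000051146, chromosome 16, 20619215 to 20621287), had 95.0 ± 31.8 against 311 ± 84.9 CPM (-1.65 ± 0.39, adjusted p = 0.377), and Bok (-3.15 ± 0.75), Slc35g2 (-2.37 ± 0.61), Unc50 (-1.48 ± 0.40) and Olfm3 (-1.64 ± 0.46) did not pass either. Without HL non-CSN replicate 2 the values were 4.09 for St6galnac5, 6.95 for Tns1, 8.59 for Serpina3n and -4.19 for Slc35g2, which stood at -1.42 without FL non-CSN replicate 1.

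In edgeR 1 of 8332 genes passed, Cdh13. The 149 higher and 153 lower genes at an unadjusted p under 0.05 were fewer in all than the 0.05 share that chance gives. DESeq2 called 2 genes, and limma voom 1. With the pair term and 1 residual degree of freedom, 8 genes were higher and 5 lower. The higher ones included Cdh13 (2.99 ± 0.64, adjusted p = 0.00432) and the L5 ET gene Crym (2.97, adjusted p = 0.000681). In this fit only FL pair 1 and HL pair 2 held both members, so the difference rests on them alone. Over all libraries of the comparison Crym had 182 ± 147 against 14.9 ± 21.0 CPM. That non-CSN mean lay under the 65.6 CPM that a count of 0 allows in FL non-CSN replicate 1. Cdh13 missed the threshold without FL non-CSN replicate 1 (adjusted p = 0.433), HL CSN replicate 1 (0.109), HL CSN replicate 2 (0.271) or HL non-CSN replicate 2 (0.603), while its log2 change stayed between 2.98 and 3.30. The number of genes called was 46 without FL CSN replicate 1, 6 without FL CSN replicate 3, 2 without HL non-CSN replicate 2, 3 without HL CSN replicate 3 and 0 without FL non-CSN replicate 1, HL CSN replicate 1 or HL CSN replicate 2. The count was also 0 under each of 6 other choices of cells, where the log2 change of Cdh13 was 2.12 with no cell filter, 2.07 with the stricter filter, 1.68 with doublets kept, 3.08 at resolution 0.5, 3.15 at resolution 2 and 2.98 in cells with at least 5000 UMIs.

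Of the nuclear oxidative phosphorylation genes in L5 ET-like cells 35 of 36 were lower in CSN libraries (median -0.61), and the list fell as a set (camera adjusted p = 7.24e-05; adjusted p = 0.791 with an estimated correlation), with Ndufa6 at -0.95 ± 0.43, Ndufb4 at -1.21 ± 0.54 and Cox6b1 at -0.90 ± 0.45. With the pair term it pointed up (adjusted p = 0.986), and with the library covariate it did not pass (0.0738). The libraries' L5 ET-like cells differed in depth: cells of the shallow cluster 8 (median 1655 UMIs, against 34770 in cluster 14) were 90.0% of them in FL non-CSN replicate 1, 23.5% in HL non-CSN replicate 2, and 3.23% to 69.6% in the CSN libraries. L5 ET identity genes had 7 of 8 above 0 (median 0.21; camera adjusted p = 0.0793), and Crym (2.29 ± 0.61) passed adjusted over the list alone. Upper layer and IT genes had 6 of 7 below 0 (0.108). Both passed camera with the pair term (adjusted p = 0.0159 and 0.0153). That fit rests on FL pair 1 and HL pair 2 alone and leaves 1 residual degree of freedom. With an estimated correlation each of these lists gave an adjusted p of 0.989 there. With the library covariate they gave 0.04999 and 0.00456. The segmental markers Crim1 (1.09 ± 0.45, passing adjusted over the list alone) and Cbln1 (-0.58 ± 1.26) gave 0.319. Among 17 cadherins (0.575) Cdh13 rose, and 1 gene was higher and 1 lower adjusted over the list alone. The area patterning list (0.843) had 1 higher gene adjusted over the list alone, and its test pointed down with a median of -0.03 and a mean of 0.14. The upper layer and IT list had 1 lower gene adjusted over the list alone, and the oxidative phosphorylation list and the other 13 lists tested had none. Above 0 were 11 of 21 neurofilament and cytoskeleton genes (0.819, median 0.08, test downward), 18 of 34 potassium and HCN channels (0.819, median 0.02, test downward), 14 of 22 sodium and calcium channels (0.575), 12 of 19 glutamate receptors (0.245), 6 of 13 GABA receptors (0.552), 7 of 11 monoamine and acetylcholine receptors (0.245), 25 of 32 axon guidance genes (0.245), 10 of 13 axon growth genes (0.541), 6 of 16 immediate early genes (0.843), 2 of 5 interferon genes (0.843, median -0.25, test upward) and 9 of 13 mitochondrially encoded genes (0.878). The single oligodendrocyte and inhibitory genes tested both gave 0.680.

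FL and HL CSN were compared within L5 ET-like cells to ask whether neurons that project to cervical and lumbar cord differ. In 2 FL libraries (replicates 1 and 3) against 3 HL libraries, Tmem158 (ENSMUSG00000054871, chromosome 9, 123259053 to 123260764) had 62.7 ± 31.4 CPM in FL and 20.04 ± 3.87 in HL (log2 1.82 ± 0.43). The adhesion gene Alcam (ENSMUSG00000022636, chromosome 16, 52248996 to 52454074) had 52.1 ± 12.2 against 11.7 ± 5.53 (1.88 ± 0.49), and the deubiquitinase gene Uchl3 (ENSMUSG00000022111, chromosome 14, 101653967 to 101696125) 67.4 ± 45.2 against 19.7 ± 8.29 (1.89 ± 0.47). Lower in FL were the cadherin gene Cdh7 (ENSMUSG00000026312, chromosome 1, 109982431 to 110140157; -1.99 ± 0.44, 22.1 ± 2.60 against 92.5 ± 28.0) and the matrix gene Npnt (ENSMUSG00000040998, chromosome 3, 132881745 to 132950291; -1.71 ± 0.42, 59.0 ± 2.44 against 188 ± 61.9). The NMDA receptor subunit gene Grin3a (ENSMUSG00000039579, chromosome 4, 49661611 to 49845744) had 25.6 ± 28.2 against 121 ± 54.7 (-2.98 ± 0.76), and Tox2 (ENSMUSG00000074607, chromosome 2, 163203125 to 163324170) 18.9 ± 1.85 against 57.7 ± 2.63 (-1.65 ± 0.43). Pigp (1.87 ± 0.46), S100a10 (1.90 ± 0.47) and Gpr161 (-2.27 ± 0.58) completed the named genes, none of which passed. Without FL CSN replicate 1 the values were nearer to 0 for Tmem158 (1.06), Uchl3 (0.80), Pigp (0.85) and Grin3a (-1.31).

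Of 3 genes named in advance as segmental markers, Crim1 (ENSMUSG00000024074, chromosome 17, 78200248 to 78376592) had 129 ± 46.8 CPM in FL and 147 ± 50.1 in HL CSN L5 ET-like cells (-0.27 ± 0.41, adjusted p = 0.999). Its sign turned without FL CSN replicate 1 (0.12) and without HL CSN replicate 3 (0.05). Cbln1 (ENSMUSG00000031654, chromosome 8, 87468405 to 87472609) had 46.8 ± 62.6 against 54.6 ± 36.2 (-0.82 ± 1.48, adjusted p = 0.999), from -4.13 to 1.00 (without FL CSN replicate 1) as single libraries were left out. Klhl14 had 4 UMIs in FL CSN replicate 1 (2.38 CPM, 0.648 to 6.09), 1 in HL CSN replicate 2 (0.467 CPM) and 4 in HL CSN replicate 3 (8.11 CPM, 2.21 to 20.8). It had none in the other CSN libraries, where a count of 0 allows up to 55.1, 14.1 and 17.1 CPM, and was not tested, so a difference in it was not detectable at this depth.

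In edgeR 0 of 7781 genes passed (lowest adjusted p = 0.835). The 245 higher and 96 lower genes at an unadjusted p under 0.05 did not exceed the 0.05 share that chance gives. DESeq2 and limma voom also called 0, but edgeR called 57 genes with the stricter cell filter and 15 with no filter on low counts. Without FL CSN replicate 1 there were 4 calls and without FL CSN replicate 3 there were 334, each with a single FL library whose spread was taken from the others. With a covariate for the division of libraries described among the other observations, 9 genes passed with 2 residual degrees of freedom, 6 higher in FL (Tmem158, Uchl3, Pigp, S100a10, Gm30382 and Crym) and 3 lower (Cdh7, Npnt and Grin3a). That division was picked from these same libraries for its high number of calls in excitatory-like cells.

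All 36 nuclear oxidative phosphorylation genes were higher in FL than HL CSN L5 ET-like cells (median 0.86), and the list rose as a set (camera adjusted p = 1.42e-08; adjusted p = 0.817 with an estimated correlation), with Ndufs8 at 1.36 ± 0.42 (130 ± 33.4 against 45.5 ± 26.1 CPM), Ndufa13 at 1.02 ± 0.40 and Ndufa1 at 1.17 ± 0.47. Cells of the shallow cluster 8 were 69.6% and 44.4% of L5 ET-like cells in these FL libraries and 28.6%, 3.23% and 12% in the HL libraries. Immediate early genes rose as a set (11 of 15 above 0, median 0.25; camera adjusted p = 0.0289; adjusted p = 0.817 with an estimated correlation), among them Btg2 (1.01 ± 0.52), Dusp1 (0.72 ± 0.41) and Fos (0.74 ± 0.43), but not with the library covariate (0.0759). Adjusted over the list alone, 1 gene was higher in each of the L5 ET identity (camera adjusted p = 0.461), area patterning (0.512) and interferon lists (0.484). By the same measure 1 was lower in each of the glutamate receptor (0.461), cadherin (0.578) and oligodendrocyte lists (0.0852, the gene Mbp at -1.21). No gene passed in this way in the other lists. These were segmental markers (0.502), upper layer and IT genes (0.909, median -0.20, test upward), neurofilament and cytoskeleton genes (0.512), potassium and HCN channels (0.909), sodium and calcium channels (0.849, median 0.02, mean -0.08, test downward), GABA receptors (0.918), monoamine and acetylcholine receptors (0.642), axon guidance (0.361), axon growth (0.512), mitochondrially encoded genes (0.512) and the 1 inhibitory gene tested (0.512).

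Over all excitatory-like cells, FL and HL CSN libraries (3 and 3) differed most by p-value in Ccnb1 (ENSMUSG00000041431, chromosome 13, 100778650 to 100786570), with 9.50 ± 0.989 against 3.63 ± 0.572 CPM (1.40 ± 0.28), and in the neuropeptide gene Cartpt (ENSMUSG00000021647, chromosome 13, 99898489 to 99901091), with 7.03 ± 3.93 against 1.08 ± 0.129 (2.69 ± 0.49). The retinoic acid hydroxylase gene Cyp26b1 (ENSMUSG00000063415, chromosome 6, 84571414 to 84593908) had 7.55 ± 4.99 against 1.43 ± 1.06 (2.40 ± 0.59). Lower in FL were the activity-regulated genes Pcdh8 (-1.56 ± 0.40; 6.60 ± 1.63 against 19.0 ± 10.2) and Ptgs2 (-0.91 ± 0.26; 11.7 ± 3.16 against 21.3 ± 0.876), and the semaphorin receptor gene Nrp2 (-1.07 ± 0.33; 6.94 ± 2.70 against 14.2 ± 1.59). Nme2 (1.86 ± 0.51), Vkorc1 (0.95 ± 0.26), Tmem74bos (-1.66 ± 0.51) and Mroh7 (-1.44 ± 0.46) were also named. Crim1 had 41.8 ± 18.1 CPM in FL and 56.5 ± 22.5 in HL (-0.46 ± 0.37), Cbln1 8.15 ± 8.50 and 11.7 ± 7.29 (-0.77 ± 0.70), and Klhl14 had at most 6 UMIs per library. It stood at 0.375 (0.138 to 0.816), 0.118 (0.00298 to 0.655) and 0 CPM (up to 1.32) in FL CSN replicates 1 to 3, and at 0 (up to 0.333), 0.166 (0.00421 to 0.927) and 0.472 CPM (0.129 to 1.21) in HL CSN replicates 1 to 3. As single libraries were left out Crim1 ran from -0.84 (without FL CSN replicate 3) to -0.17 and Cbln1 from -1.85 (without FL CSN replicate 3) to -0.16 (both without HL CSN replicate 2).

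None of 12612 genes passed in edgeR (adjusted p = 1.00 for each gene named). At an unadjusted p under 0.05 lay 93 higher and 68 lower genes, fewer in all than the share of 0.05 that chance gives. DESeq2 called 1 gene and limma voom 0. No list passed camera in the fit with neither the library covariate nor the replicate number as a block. With the replicate number as a block, which does not pair these libraries, oxidative phosphorylation genes gave 0.0484 (adjusted p = 0.895 with an estimated correlation). With the covariate oxidative phosphorylation genes passed as higher (median 0.55, camera adjusted p = 2.96e-17) and axon guidance genes (0.0115), cadherins (0.0115) and glutamate receptors (0.0162) as lower, at the preset correlation. With an estimated correlation and no covariate these gave adjusted p of 0.897, 0.897, 0.823 and 0.897. With neither the lowest adjusted p was 0.109, for oxidative phosphorylation (36 of 36 above 0, median 0.28), mitochondrially encoded (9 of 13 above 0) and L5 ET identity genes (6 of 9 below 0, median -0.75). Cyp26b1 of the area patterning list (0.232) passed adjusted over the list alone, and no gene of another list did. The segmental, neurofilament, cadherin, axon growth and inhibitory lists each gave an adjusted p of 0.150, and axon guidance and endothelial genes gave 0.232. The others ranged from 0.345 (oligodendrocyte) to 0.845 (immediate early, median 0.12, mean -0.04 and test downward): upper layer and IT genes and microglia 0.567, potassium and HCN channels 0.456, sodium and calcium channels 0.785, glutamate and GABA receptors 0.783, monoamine and acetylcholine receptors and interferon genes 0.766 and astrocytes 0.801. For the interferon list (median 0.05, mean 0.04) the test pointed down.

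FL and HL non-CSN libraries were compared to ask whether neighbouring cells differ between limb areas. None of the genes named here passed, and their values were not separated from the mix of cells. Cacng7, which codes for an AMPA receptor auxiliary subunit (ENSMUSG00000069806, chromosome 7, 3332955 to 3368221), had 46.8 ± 17.0 CPM in FL and 11.2 ± 2.75 in HL (2.12 ± 0.31; n = 3 and 3). The mitochondrial leucyl-tRNA synthetase gene Lars2 (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666) had 710.5 ± 248 against 216 ± 61.3 (1.72 ± 0.31), and Dact2 86.7 ± 28.0 against 41.4 ± 3.21 (1.04 ± 0.24). Deptor had 33.5 ± 8.45 against 58.0 ± 5.27 (-0.76 ± 0.22). It was among the leading genes of the L4/5 IT-like cluster 6. That cluster held 18.4%, 2.82% and 0 (up to 9.68%) of L4/5 IT-like cells in FL non-CSN replicates 1 to 3. In HL non-CSN replicates 1 to 3 it held 18.6%, 20.4% and 13.8%. Nme2 (2.16 ± 0.44) and the amino acid transporter gene Slc7a5 (1.03 ± 0.26) were also higher, and Rmst (-1.64 ± 0.43), Pcdh15 (-0.71 ± 0.22) and Dgkg (-0.79 ± 0.25) lower. Crim1 stood at -0.51 ± 0.26 (-0.28 without HL non-CSN replicate 2) and Cbln1 at -0.49 ± 0.54, from -1.48 (without FL non-CSN replicate 1) to -0.15 (without FL non-CSN replicate 2).

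None of 12485 genes passed in edgeR (lowest adjusted p = 0.814). The 140 higher and 41 lower genes at an unadjusted p under 0.05 were fewer in all than the 0.05 share that chance gives. DESeq2 called 3 genes and limma voom 95. The endothelial genes Cldn5 (2.06 ± 0.54; 2.28 ± 0.598 against 0.501 ± 0.226 CPM) and Itm2a (1.34 ± 0.42) rose as a set (median 1.70; camera adjusted p = 2.99e-05; adjusted p = 0.182 with an estimated correlation), and both passed adjusted over the list alone. Mitochondrially encoded genes rose as a set (12 of 13 above 0, median 0.32; camera adjusted p = 0.0234; adjusted p = 0.683 with an estimated correlation), with mt-Atp8 at 1.34 ± 0.45. No gene of the other lists passed adjusted over the list alone. Inhibitory markers had 6 of 6 above 0 (median 1.74, adjusted p = 0.306). Segmental markers and both channel lists gave an adjusted p of 0.0743, immediate early genes 0.0830, L5 ET identity 0.0999, cadherins 0.133 (0.0369 and lower with the library covariate), oxidative phosphorylation 0.152 (0.000162 and turned upward with it), axon growth 0.234, microglia 0.274, area patterning 0.502, GABA receptors 0.529, and neurofilament, axon guidance and oligodendrocyte genes 0.615. The values with the covariate are from camera at the preset correlation only. Astrocyte markers gave 0.615 (median 0.23, test downward), upper layer and IT genes 0.825 (median 0.23, test downward), glutamate receptors 0.887 (median -0.05, mean 0.07, test downward), interferon genes 0.831 (median -0.03, test upward) and monoamine and acetylcholine receptors 0.791.

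The interaction asked whether the limb difference was the same in CSN and non-CSN libraries. Gene values below were not separated from the mix of cells. Deptor differed by 0.86 ± 0.27 on the log2 scale, Fhad1 by 0.80 ± 0.27, Rmst by 1.50 ± 0.51, Eln by 3.10 ± 1.13 and Rimbp3 by 2.04 ± 0.76. The complement gene C1qb (-3.77 ± 1.26), the GDNF receptor gene Gfra1 (-1.32 ± 0.49), Tmem169 (-0.69 ± 0.26), the Notch ligand gene Dner (-0.86 ± 0.33) and the palmitoyltransferase gene Zdhhc15 (-1.00 ± 0.39) were negative. In edgeR 0 of 13030 genes passed (adjusted p = 1.00 for each). The 22 positive and 29 negative genes at an unadjusted p under 0.05 were fewer in all than the 0.05 share that chance gives. DESeq2 and limma voom also called 0. Without FL CSN replicate 2 C1qb stood at -6.51, and without FL non-CSN replicate 1 Gfra1 stood at -0.77 and Rimbp3 at 3.63. Macrophage-like cells, whose cluster carried complement transcripts, were 30.1% of HL CSN replicate 2. Within L5 ET-like cells, where the non-CSN side is 1 FL library of 10 cells against 1 HL library of 34 cells, the values for Dner (0.35) and Zdhhc15 (6.04) had the opposite sign, which such a comparison cannot settle.

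Oxidative phosphorylation genes had a more positive limb difference in CSN than in non-CSN libraries (34 of 36 above 0, median 0.39; camera adjusted p = 0.0132; adjusted p = 0.998 with an estimated correlation). So did immediate early genes (13 of 19 above 0, median 0.16; camera adjusted p = 0.0456; adjusted p = 0.616 with an estimated correlation), with Npas4 at 1.16 ± 0.63 and Fos at 0.69 ± 0.41. The 3 endothelial genes had a more negative one (median -1.06; camera adjusted p = 0.0150; adjusted p = 0.459 with an estimated correlation). Neither the immediate early nor the endothelial list passed with the pair term (adjusted p = 0.0671 for each). No gene of these lists or of those that follow passed adjusted over the list alone. Inhibitory markers had 7 of 7 below 0 (median -1.84, adjusted p = 0.997). The segmental (median -0.12, test upward), L5 ET identity, glutamate receptor, cadherin (median -0.01, test upward), area patterning (median -0.12, test upward) and axon growth lists (median 0.03, test downward) also gave 0.997. Sodium and calcium channels and astrocyte genes gave 0.206, axon guidance 0.246, oligodendrocyte genes 0.290, GABA receptors 0.507, neurofilament genes and potassium and HCN channels 0.615, mitochondrially encoded genes 0.687, upper layer and IT genes 0.699 (median -0.33, test upward), and interferon genes (median 0.03, mean -0.05, test upward) and monoamine and acetylcholine receptors 0.987. None of the list calls in any comparison held with an estimated correlation or in fry (lowest adjusted p = 0.0711).

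The Rbp4 libraries were described without tests. In the FL positive library L5 ET-like cells were 12.7% of kept cells (241 of 1900, 11.2 to 14.3), L4/5 IT-like cells 31.8% (29.8 to 34.0), unresolved excitatory-like cells 48.4% (46.1 to 50.6), L2/3 IT-like cells 2.26% (1.64 to 3.04) and inhibitory-like cells 0.789% (0.443 to 1.30). The library labelled negative had 26.7% L5 ET-like (625 of 2338, 24.9 to 28.6), 26.1% L4/5 IT-like (24.4 to 28.0), 40.9% unresolved (38.9 to 43.0), 1.07% L2/3 IT-like (0.693 to 1.57) and 0.770% inhibitory-like cells (0.457 to 1.21). The library labelled HL positive had 0.377% L5 ET-like (9 of 2389, 0.172 to 0.714), 65.7% L2/3 IT-like (63.7 to 67.6), 8.96% L4/5 IT-like (7.84 to 10.2), 6.15% L6 CT-like (5.22 to 7.19) and 6.07% inhibitory-like cells (5.15 to 7.1). tdTomato stood at 16.3 CPM in L5 ET-like cells and 29.9 in other excitatory-like cells of the FL positive library, and at 18.8 and 28.7 in the library labelled negative. Because tdTomato went against these labels, no limb difference was drawn from the Rbp4 libraries.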

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

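Tests of exchanged labels, of reads carried over, of few labelled hindlimb cells, of cells collected without the label, of the unresolved class, of the cell filter, of free RNA and of the mix of excitatory classes were chosen after the results were seen.

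In 2 Rbp4 libraries the reporter and the cell classes went against the labels, and tdTomato at 26.2 CPM in the library labelled negative was the signal that drew attention to them. Reads carried over from the FL positive library are argued against, since the library labelled negative had 169% as many tdTomato UMIs, and a scarcity of labelled L5 ET cells in hindlimb cortex, the biological alternative, would not give the library labelled negative 0.900 times the FL positive level. An exchange of the labels of the libraries labelled HL positive and negative is a candidate explanation: the library labelled HL positive had 0.217 CPM of tdTomato, under the limit of 2.55 that the non-CSN libraries set, and 0.377% L5 ET-like cells against 26.7%. Whether the library labelled negative holds hindlimb cells cannot be told apart from other origins, with 1 library on each side. Of the 9 genes called between FL and HL CSN with the covariate, 3 (33.3%) differed in the same direction. Signed by the CSN direction, their median log2 difference was -0.31, at percentile 0.42 of 10000 expression-matched random lists. That percentile compares genes between 1 library on each side and measures no spread between libraries. The 9 calls also rest on a covariate picked from the retrograde libraries, so no conclusion on the origin of the cells is drawn. Under such an exchange the FL positive and HL positive libraries would both be rich in L5 ET-like and L4/5 IT-like cells.

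L5 ET-like cells were a minority in every library sorted for retrograde GFP, at most 11.9% of kept cells. Loss to the unresolved excitatory class is argued against, since the sum of both classes reached at most 22.9%, and so is loss to the cell filter, since among all barcodes the highest L5 ET-like share was 8.60%. Collection of cells without the label may account for it in FL CSN replicate 1, where eGFP CPM in other excitatory-like cells was 0.0103 of that in L5 ET-like cells, and FL CSN replicate 3 pointed the same way from 3 UMIs (14.1 CPM, 2.91 to 41.2, against 0, up to 1.46). It stays open in the others, since HL CSN replicate 2 had 0.467 CPM (0.0118 to 2.60) in L5 ET-like and 0.776 (0.160 to 2.27) in other excitatory-like cells, and whether the eGFP sequence or the mapping differed between libraries was not tested. No biological explanation was tested, since the design has no group in which other classes carry the virus.

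In the CSN against non-CSN comparison of excitatory-like cells, a larger L5 ET-like share may explain the L5 ET identity list, whose median over 7 genes went from 0.82 to -0.00669 without those cells, in part by construction, since their clusters were named from shared markers. That same -0.00669 in the remaining cells argues against free RNA from L5 ET cells. For the 46 genes called higher with the pair term (median 0.81) the share is argued against as the whole cause by the median of 0.57 without L5 ET-like cells, and a different mix of excitatory classes by that of 0.74 within L4/5 IT-like cells alone. That class pools 4 clusters, so 0.74 does not bear on their mix. A different mix of L4/5 IT-like clusters is a candidate explanation. Within single clusters the median was 0.27 (cluster 4, 27 genes tested), 0.16 (cluster 6, 41) and 0.39 (cluster 7, 39), below 0.81 by more than its spread. Each met the limit set beforehand for this explanation, but cluster 7 did so by less than its spread. Since 0.81 covers all 46 genes, part of the drop may come from the genes not tested. A biological difference between the sorts within 1 cluster stays open, since the pair term called 54 genes in cluster 4, 0 in cluster 6 and 7 in cluster 7 (0 in each without it). Of these, 1, 0 and 1 were among the 46, and 8, 0 and 0 among the 43 genes called lower with the pair term. Those 43 had a median of -0.69 over all excitatory-like cells. It was -0.33, -0.26 and -0.32 within clusters 4, 6 and 7, where 38, 34 and 31 were tested.

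Single libraries stood far from the other 5 of their sort in 11 of 38 sets of values by Dixon's outlier test. Its nominal rate of 5% assumes independent, normally spread values. Shares bounded at 0 from libraries of unlike size do not meet this, so no excess over chance is drawn from the count. FL CSN replicate 2 had 3.47% L5/6 NP-like cells (others 0.453% to 1.53%). It also had 35.2% L6 CT-like cells (others 5.23% to 14.6%). HL CSN replicate 2 had 40.7% excitatory-like cells (others 70% to 86.4%) and 30.1% macrophage-like cells (others 0.151% to 3.33%). FL CSN replicate 1 had 18.2 CPM of eGFP (others 0 to 0.839), which was also a signal from a feature outside the gene comparisons. FL non-CSN replicate 2 had 5.20% L5/6 NP-like (others 0.134% to 1.64%), 9.60% astrocyte-like (others 0 to 2.63%) and 0.80% microglia-like cells (others 0 to 0.202%). FL non-CSN replicate 1 had 22.2% unresolved excitatory-like cells (others 0 to 5.35%). HL non-CSN replicate 2 had 1.69% macrophage-like cells (others 0 to 0.400%) and 0.0678 CPM of eGFP (others 0). That eGFP level lies under the limits that a count of 0 allows in the other 5 (0.127 to 2.55 CPM), so it does not set the library apart. Counting error also spans the gap for microglia-like cells (2 of 250, 0.0970% to 2.86%), since 0 of 76 cells in FL non-CSN replicate 3 allows up to 3.95%. For macrophage-like cells of HL non-CSN replicate 2 (1.32% to 2.13%) it spans the gap to that library and to FL non-CSN replicate 2 (up to 2.21%). It does not reach FL non-CSN replicate 1, HL non-CSN replicate 1 or HL non-CSN replicate 3, where a count of 0 allows up to 0.0805%, 0.535% and 0.607%. The intervals of L5/6 NP-like cells overlapped others too, 2.80% to 8.73% with up to 7.11% in non-CSN libraries and 2.32% to 4.98% with up to 2.98% in CSN libraries.

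The limb difference itself differed between CSN and non-CSN libraries in 4 lists by camera: immediate early genes (adjusted p = 0.0456), oxidative phosphorylation genes (0.0132), microglia markers (0.00741) and endothelial markers (0.0150). None of these held with an estimated correlation, and with the pair term only oxidative phosphorylation genes passed.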

How the results depend on the processing

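Chosen after seeing the data were the tests with the library covariate, with at least 5000 UMIs per cell, and on sums of chosen classes or clusters; the cause of each difference below was not tested unless stated. Of the named genes, 1823 of 1838 values kept their direction. Apart from the segmental markers these genes were picked by p-value or size of change in the same libraries. Most settings reuse the same counts, so a kept direction is no independent support. Of the comparison results, 150 stayed within 1.5 times or on the same side, 61 moved and 5 turned.

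CSN against non-CSN, excitatory-like cells, called 24 genes with DESeq2, 9 with voom, 89 with the pair term, 17 with the covariate, and 0 within FL or within HL libraries, which have fewer samples. Without L5 ET-like cells and with the pair term it called 39. It called 0 in L4/5 IT-like cells (401 with the pair term), 0 and 0 in L6 CT-like cells, 0 in cluster 4 (54), 0 and 0 in cluster 6, and 0 in cluster 7 (7). In L6 CT-like cells Tmem91 turned to -0.38 (pair term -0.46). In cluster 6, Sulf2 turned to -0.0126 (-0.12), Tmem91 to -0.0578 (-0.13), Parm1 to -0.45 (-0.49), Slc17a6 to 0.23 without and Dact2 to 0.0751 with the pair term. Left-out libraries gave 0 to 1 genes.

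In L5 ET-like cells the sort comparison called 2 genes with DESeq2, 17 with no filter on low counts, 13 with the pair term, 4 within FL and 20 within HL (each with 1 non-CSN library, assumed to vary like the others), 9 with the covariate, and 0 with no cell filter, the stricter filter, doublets kept, resolution 0.5, resolution 2 or at least 5000 UMIs; left-out libraries gave 0 to 46. The oxidative phosphorylation list turned with the pair term (adjusted p = 0.986). The limb comparison of CSN called 15 with no filter on low counts, 57 with the stricter cell filter, 2 with the replicate number as a block and 9 with the covariate; left-out libraries gave 0 to 334. There Crim1 ran from -0.65 to 0.12 and Cbln1 from -4.13 to 1.00.

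In excitatory-like cells DESeq2 called 1 gene between FL and HL CSN and 3 between FL and HL non-CSN, where voom called 95. The oxidative phosphorylation list turned upward between FL and HL non-CSN with the covariate (camera adjusted p = 0.000162, at the preset correlation only). Left-out libraries gave 0 to 0 genes in both and in the interaction, where Dner turned to 0.35 and Zdhhc15 to 6.04 in L5 ET-like cells, with 1 non-CSN library per limb. With the replicate number as a block oxidative phosphorylation genes passed between FL and HL CSN (0.0484) and immediate early genes between FL and HL non-CSN (0.0214). Both are camera values at the preset correlation only.

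Classes whose share passed between CSN and non-CSN numbered 1 with no cell filter, 1 with the stricter filter, 1 with doublets kept, 2 at resolution 2, 1 with at least 5000 UMIs, and 0 to 1 with left-out libraries (FL against HL 0 to 0). With doublets kept the macrophage-like difference turned to -0.273 points. The L5 ET-like difference ran from 4.39 to 6.65 points with left-out libraries. Between FL and HL CSN it ran from -1.13 to 4.52, and was -0.437 with the stricter filter, -1.91 as a share of excitatory-like cells and -1.82 with at least 5000 UMIs. Of 13 list calls, 0 held with an estimated correlation and 0 in fry.

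Few cells limit the L5 ET-like results: at least 30 cells per library could not be fitted for either comparison there, and of the non-CSN libraries only FL replicate 1 and HL replicate 2 had 10 or more such cells.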

Other observations

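The tests with the library covariate were chosen after the data were seen, and the counts of other divisions of the libraries were planned before. The L4/5 IT-like cells fell into 4 clusters whose mix differed between sorts. Cluster 4, led by Rorb, Rspo1 and Cartpt, held 35.2% ± 9.71 of L4/5 IT-like cells in CSN libraries and 61.7% ± 21.1 in non-CSN libraries (SD, n = 6 and 6), and was higher in CSN in 0 of 6 pairs. Cluster 6, led by Deptor, Tmem91, Il1rapl2 and Wnt7b, held 33.9% ± 7.98 against 12.4% ± 8.80, higher in 6 of 6 pairs. Cluster 7, led by Scn7a, Tnnc1 and Endou, held 27.7% ± 5.54 against 17.5% ± 4.78, also in 6 of 6 pairs, and cluster 9 held 3.10% ± 3.4 against 8.45% ± 17.4, higher in 2 of 6 pairs. Its non-CSN mean came from FL non-CSN replicate 1 (43.7%; others 0 to 5.93%), so no difference is drawn from it. In the FL positive Rbp4 library clusters 4 and 6 held 3.97% and 32.2% of these cells, in the library labelled negative 5.24% and 42.1%, and in the library labelled HL positive 59.3% and 17.3%.

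Macrophage-like cells formed 2 clusters. Cluster 18, with Mrc1, C1qa and Pf4, held all 184 macrophage-like cells of HL CSN replicate 2, which had 612 kept cells. Cluster 25, with the MHC class II genes H2-Aa, H2-Ab1 and Cd74, held 70 cells, all from HL non-CSN replicate 2. Transcripts of 4 Y-linked genes had 0 UMIs in FL CSN replicate 3 (up to 0.839 CPM) and FL non-CSN replicate 3 (up to 2.55 CPM), where Xist stood at 408 and 601 CPM. In FL CSN replicate 1 Xist stood at 0.734 CPM and the Y-linked genes at 174 CPM, and in its partner FL non-CSN replicate 1 they stood at 54.1 and 110 CPM. These values go against the pooling of males and females that the labels give for FL CSN replicates 1 and 3 and FL non-CSN replicate 3. The FL libraries of the L5 ET-like limb comparison, replicates 1 and 3, thus differed in sex, and the members of FL pair 1 differed in their mix, which the pair term does not remove.

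Other divisions of the same libraries were tried for the excitatory-like cells. For CSN against non-CSN, 5 of 100 divisions drawn from 462 called at least the 1 gene of the real one, and the highest other called 28, so chance cannot be excluded for that count. With the pair term, where only the members of pairs trade places, 1 of 32 divisions, the real one, reached 89 genes, and the highest other called 3. A share of 1 in 32 is the smallest that this test can reach, so chance is unlikely for that count but not excluded. FL against HL in CSN and in non-CSN libraries has 10 divisions each, too few for a share under 0.05: the real values were 0 and 0 and the highest others 1272 and 1551. For the interaction the real count was 0, which all 100 divisions drawn from 200 reach by construction, so the test says nothing on chance; the highest other called 1.

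The highest division was the same in CSN and non-CSN libraries, FL replicate 1, HL replicate 1 and HL replicate 2 against FL replicate 2, FL replicate 3 and HL replicate 3. It points to a structure of the samples that the labels do not give. With it as a covariate CSN against non-CSN called 17 genes (6 higher, 11 lower), all 17 of which were also called with the pair term. The division was picked from these same libraries for its high count, and it is constant within each pair. The overlap is thus no independent support, and all calls with the covariate rest on that choice. In L5 ET-like cells 9 genes were called between sorts and 9 between limbs, and in excitatory-like cells the limb comparisons and the interaction called 0, with 1063 (CSN), 741 (non-CSN) and 196 (interaction) at an unadjusted p under 0.05 in edgeR.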
